A study of Mus musculus with 8 samples.

How the data were processed

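The series holds inDrops single-cell RNA libraries (polyA RNA, paired-end sequencing) from subcutaneous D4M.3A-pOVA melanomas of 2 mice, 4 libraries per animal, per the labels. Live CD45-positive and CD45-negative cells were sorted and mixed at a ratio that favours immune cells, per the labels' protocols, so the shares of immune and other cells reflect the sort. The submitters' processing notes name bcl2fastq, Seurat, GRCm38 and mm10 without versions. The aligner and the UMI counter are not given in the sources used here. Doublets and stressed or dead cells had been removed from the annotated cells, per the labels.

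The authors deposited 3 kinds of values. The raw matrices hold UMI counts per gene and barcode with no normalization, per the file headers, for 19274 barcodes and 53468 gene IDs, of which 53363 matched a gene symbol. The matrix of the 8757 annotated cells and 20679 genes, as deposited by the authors, holds depth-corrected counts, which are a score of a normalization and not UMIs: they are whole numbers, but the cell totals lie in a narrow range and follow the depth of the cell only in part. In cDC1, for example, median corrected totals were 868 and 1173 in animals 1 and 2, where median UMI totals were 597 and 1309. The annotation gives each cell's library, animal, state, UMI total, corrected total and percent of mitochondrial UMIs, per the file headers, and 6 further columns were not used. No annotated cell could be matched to the UMI matrices: 174 annotated cells had a barcode in the UMI matrices (138 expected by chance), the highest cosine similarity between any annotated cell and any barcode was 0.396, and 300 of 300 thinned control barcodes found themselves (median 0.847). The controls were thinned UMIs and not corrected counts, so a shared annotated cell might reach a lower value. A small overlap of the 2 sets is not excluded. The annotated cells were therefore analysed from corrected counts, and the UMI matrices as a second set of cells. Raw totals ran from 1682997 to 4709795 UMIs per library.

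Corrected counts were summed per animal and state, or per animal and major population, and divided by their total to give levels per 1e+06. The states Mast cells and Neu had under 10 cells in an animal and were left out of all tests. Comparisons used limma 3.58.1 in R 4.3.3 (robust empirical Bayes) on log2 of the level plus a pseudocount of 50, with weights proportional to the summed counts and capped at 2e+05, for genes with at least 50 per 1e+06 in both animals of at least 1 compared population. Adjustment was by Benjamini-Hochberg with a threshold of 0.05. The compared populations come from the same animals, so the animal was a block, and n is 2 animals in every main test. The alternative with sums per library counts the libraries of an animal as separate units. Cells were not treated as replicates. Each major population was set against the mean of the other 7, each T or NK state against the mean of the other 3, each conventional dendritic state against the mean of the other 2, CD8 T E against CD8 T M, and DC3 against the mean of cDC1 and cDC2. CD8 T E was taken as the effector state and CD8 T M as the memory, stem or naive-like state from their names, although the annotation does not spell out the letters.

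The design fixed before the data were examined had planned edgeR on summed UMI counts with all populations in 1 fit. limma replaced it because the annotated cells come as corrected values. The fit was narrowed to the compared populations after tests on simulated data, in which several versions were tried, before any contrast was computed on the real values but after the levels of some genes had been seen. In simulated data 8.59% of the calls in CD8 T E against CD8 T M were false (19.5% with all populations in the fit), 2.25% for DC3 (5.83%), 3.03% for NK cells (14.1%), 2.56% for cDC1 (10.3%), 7.22% for T cells and 5.88% for B cells. Changes of 2, 4 and 8-fold were recovered in 32.8%, 92.2% and 98.6% of genes for CD8 T E against CD8 T M, in 7.25%, 42.9% and 85.2% for DC3, and in 0%, 0% and 51.6% for B cells. All simulations, also those of the UMI set, drew Poisson counts around real levels, in 1 run per comparison. The spread between sums was set by hand, and the changed genes came from a limited range of levels. The spread in the real data may differ, so these rates hold for those settings only.

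The 18 gene lists and the markers were fixed before the data were examined. They cover chemokine receptors, chemokines, cytotoxic effectors, inhibitory receptors and exhaustion, stem, memory and naive T cell genes, common gamma chain cytokine receptors, IL-2 and IL-15 target genes, apoptosis and survival, cytokines that act on T cells, IL-15 trans-presentation, costimulatory and coinhibitory ligands, MHC class I and class II presentation, interferon-stimulated genes, proliferation, integrins and adhesion, dissociation and stress, and glycolysis. Cxcr6, Cxcl16, Il15, Il15ra, Ccr7 and Tcf7 were always named. In the main comparisons the rule then named, per list, up to 2 genes per direction past the threshold with the highest level, and up to 6 genes per direction outside the lists and markers with the largest log2 fold change, at 50 or more per 1e+06 in both animals and with the same sign in both. Other named genes were chosen after their values were seen. Shares of cells have exact (Clopper-Pearson) 95% intervals, which hold counting error only. For shares of cells with a count, each cell was also thinned to 500 corrected counts, which does not equalise the UMI depth of cells. Depth was therefore tested with the cells of the higher state at or below the median UMI total of the lower state, set against cells of the lower state at or above it. These cells were chosen by UMI total but scored on corrected counts, so depth need not favour the lower state. Gene positions are from GENCODE vM21.

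In the UMI set, barcodes with more than 350 and fewer than 6000 UMIs, more than 250 genes, a ratio of log10 genes to log10 UMIs above 0.9 and under 10% mitochondrial UMIs were kept, 10435 in all. They were clustered in scanpy 1.11.5 with python 3.11.15 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1), and the T and NK cells and the dendritic cells were clustered again. A cluster was named when at least 3 markers were raised 2-fold. Scrublet called 41 barcodes (0.393%), taken as a sign that it did not work here, so doublets were kept, and the 5% with the highest scores were left out as an alternative. Naming and doublet handling were settled after the clusters were seen. No cluster could be named DC2-like on reclustering, so DC3-like cells were set against all other clusters of the dendritic group except pDC-like ones, and as an alternative without the cluster that had more macrophage than dendritic markers among its top 10 genes, a choice made after the Cxcl16 levels of the clusters had been seen. UMIs summed per animal and cluster were tested with edgeR 4.0.16 (quasi-likelihood, TMM, animal as a block). In simulated data 2.80% of the CD8 calls and 4.85% of the DC3 calls against DC1 were false.

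Alternatives were DESeq2 1.42.0 (test and size factors, UMI set), no filter, no block, all populations in the fit, sums per library, at least 30 cells per sum, other pseudocounts, equal weights, levels per 1000 cells, pDC included, only the CD8 states, CD8 T M limited to CD8 cells, labels set anew from 20 neighbours without the list genes (88.2% of all cells kept their label, but 54.6% of cDC1, 63.0% of cDC2, 81.5% of DC3, 79.0% of CD8 T M, 84.1% of CD4 T R/H, 91.6% of CD8 T E and 6.82% of Mono4), thinning, means over cells or over libraries, and each animal left out.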

Results

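Single-cell transcriptomes were measured in subcutaneous tumours of D4M.3A-pOVA, a BRAF-mutant and PTEN-null mouse melanoma line that carries an ovalbumin peptide as a model antigen. Tumours of 2 C57BL/6 animals were taken on day 17 after implantation, live cells were sorted to enrich CD45-positive (immune) cells, and 4 inDrops droplet libraries were made from each animal. All 8 libraries belonged to 1 group, so the comparisons are between cell populations of the same tumours. The deposited annotation held 8757 cells in 17 states, 3332 cells from animal 1 and 5425 from animal 2. The UMI totals of the annotated cells ran from 822662 to 2146608 per library, and the median cell of a library had 902.5 to 1284 UMIs. Levels are given as the authors' corrected counts per 1e+06 corrected counts of a state in 1 animal, as mean ± SD of the 2 animals. State names are those of the annotation, which does not spell out the letters E, M, R and H.

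Myeloid cells made up most of the annotated cells. The macrophage state Mac1 held 30.2% ± 2.34 (SD, n = 2 animals) of the cells and the monocyte state Mono1 held 22.9% ± 3.05. Non-immune cells followed with 17.5% ± 0.190, a share set in part by the sort. Among lymphocytes, CD8 T E held 6.45% ± 1.39, NK cells 4.97% ± 0.871, CD8 T M 3.78% ± 1.15, CD4 T R/H 3.16% ± 0.841 and B cells 0.415% ± 0.0919. The dendritic states were small: cDC2 held 2.12% ± 0.237, cDC1 2.06% ± 0.438, pDC 0.839% ± 0.168 and DC3 0.579% ± 0.224. DC3 rested on 14 cells of animal 1 (0.420%, exact Clopper-Pearson 95% interval 0.230 to 0.704) and 40 cells of animal 2 (0.737%, interval 0.527 to 1.00). These intervals cover counting error only. The remaining states were Mono2 (2.12% ± 1.43), Mac2 (1.40% ± 0.191), mast cells (0.874% ± 1.18), Mono4 (0.521% ± 0.112) and neutrophils, named Neu (0.192% ± 0.145). No test was made on shares.

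The next comparison asked which cells of the tumour carry chemokine receptors and their ligands. Cxcr6, the receptor of the chemokine Cxcl16, was a T cell gene: its level was 689 ± 265 in T cells and 10.4 on average over the other 7 major populations, a log2 fold change of 3.61 ± 0.18 (SE, n = 2 animals, adjusted p = 4.73e-09, limma with Benjamini-Hochberg adjustment). By state, CD8 T E contributed 83.0% ± 3.60 of all Cxcr6 counts, CD8 T M 7.55% ± 0.759 and CD4 T R/H 3.76% ± 2.51. Cxcl16 had the reverse distribution. It was higher in macrophages (715 ± 65.8, log2 fold change 2.83 ± 0.16), monocytes (379 ± 10.3, 1.88 ± 0.16) and conventional dendritic cells (365 ± 104, 1.83 ± 0.17) than in the mean of the other populations, and lower in T cells (-1.48 ± 0.16), NK cells (-1.36 ± 0.16), pDC (-1.67 ± 0.30) and non-immune cells (-1.06 ± 0.16). Mac1 contributed 61.7% ± 2.57 of the Cxcl16 counts, Mono1 28.2% ± 1.87 and DC3 1.58% ± 0.748. Il15, a survival cytokine of T and NK cells, was too low to be tested in any major population. Of its counts 47.8% ± 5.52 came from Mono1 and 32.7% ± 7.93 from Mac1. Il15ra, which presents Il15 to other cells, was higher in monocytes (0.65 ± 0.15) and lower in NK cells (-0.43 ± 0.15).

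Several other receptors and ligands were shared between populations. Ccr2 was higher in monocytes (log2 fold change 2.46 ± 0.22), NK cells (1.91 ± 0.23) and macrophages (0.84 ± 0.22), Cx3cr1 in macrophages (2.47 ± 0.18) and monocytes (1.13 ± 0.18), and Ccr1 in monocytes (2.44 ± 0.23) and macrophages (1.85 ± 0.23). Of 14 chemokine receptors tested, 7 were higher and 4 lower in monocytes (7 and 4 adjusted over the list alone), and 5 higher and 5 lower in NK cells (5 and 5). In macrophages 5 were higher and 4 lower (5 and 6 adjusted over the list alone), and in T cells 4 and 2 (4 and 2). Xcl1, a ligand of cross-presenting dendritic cells, was higher in NK cells (1407 ± 123, log2 fold change 4.52 ± 0.12), Ccl5 in NK cells (3.31 ± 0.32) and T cells (2.96 ± 0.31), and Ccl4 in T cells (1.96 ± 0.22). Macrophages had more Ccl12 (3.49 ± 0.20) and Cxcl9 (2.87 ± 0.18), monocytes more Cxcl10 (2.65 ± 0.19), dendritic cells more Ccr7 (3.06 ± 0.20) and Cxcl9 (2.28 ± 0.19), and pDC more Ccr9 (5.19 ± 0.21). Non-immune cells had more Cxcl12 (3.24 ± 0.14) and Cx3cl1 (1.86 ± 0.13). Of 18 chemokines tested, 12 were higher, 1 was lower and 5 did not pass in macrophages (13 higher and 1 lower when adjusted over the list alone). In monocytes 11 were higher, 3 lower and 4 did not pass (11 and 3 adjusted over the list alone). In T cells 4 were higher, 12 lower and 2 did not pass (4 and 13 adjusted over the list alone). Over 5789 genes tested, 2016 passed the threshold in T cells, 2109 in NK cells, 1290 in dendritic cells, 759 in pDC, 1934 in monocytes, 1448 in macrophages, 2678 in non-immune cells and 109 in B cells, which had 16 and 19 cells. States had been built from the same transcriptomes, so genes that define a state are no independent evidence for it, here and in every comparison that follows. With the animal as a block, the p-values measure how far the differences between populations varied between the 2 animals. That spread was pooled over the populations in a fit and moderated over genes.

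**Figure D1:**
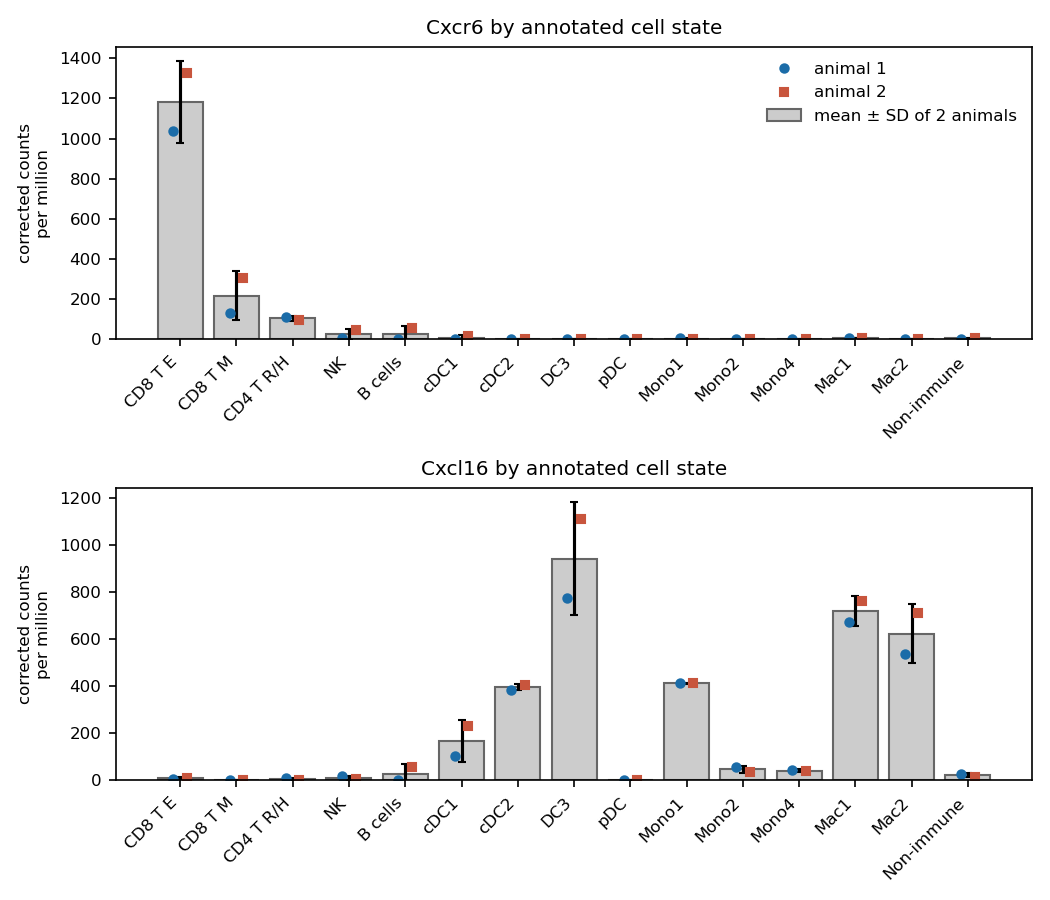
Levels of Cxcr6 (top) and Cxcl16 (bottom) in 15 annotated cell states, in the authors' corrected counts per 1e+06. Grey bars are means and whiskers SDs of the 2 animals, and points are the single animals: Cxcr6 stood at 1183 in CD8 T E and 218 in CD8 T M, and Cxcl16 at 943 in DC3, 719 in Mac1 and 168 in cDC1. Mast cells and Neu, with under 10 cells in an animal, are left out.

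Within the T and NK cells, the question was which states carry Cxcr6 and other receptors, each state being set against the mean of the other 3. In CD8 T E, Cxcr6 was 1183 ± 203 against 116, a log2 fold change of 3.11 ± 0.22 (SE, n = 2 animals, adjusted p = 2.2e-05, limma with Benjamini-Hochberg adjustment), and it was higher in both animals. Cxcr6 was lower in NK cells (25.2 ± 27.6, log2 fold change -2.31 ± 0.22) and in CD4 T R/H (105 ± 11.2, -0.90 ± 0.24). In CD8 T M it stood at 218 ± 122, with a log2 fold change of 0.10 ± 0.23 that did not pass. The gene (ENSMUSG00000048521) lies on the plus strand of chromosome 9 at 123806475 to 123811760 of GRCm38.

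Shares of cells with a Cxcr6 count followed the same order. In CD8 T E 52.7% of the 182 cells of animal 1 and 63.8% of the 403 cells of animal 2 had a count, with median corrected totals of 922 and 980. In CD8 T M 8.50% of 153 and 16.8% of 161 cells did (medians 880 and 878), in CD4 T R/H 3.20% and 5.76% (858 and 900), and in NK cells 0.538% and 2.97% (861 and 879). Mac1, taken as the background because macrophages should lack Cxcr6, had 0.283% and 0.452% at medians of 922 and 1046. After each cell was thinned to 500 corrected counts, with 0 cells left out as too shallow, the shares were 30.2% (exact Clopper-Pearson 95% interval 23.6 to 37.5) and 41.4% (36.6 to 46.4) in CD8 T E against 5.23% (2.28 to 10.0) and 12.4% (7.76 to 18.5) in CD8 T M, and 0.283% and 0.323% in Mac1. Corrected totals follow the UMI depth of a cell only in part, so this thinning does not equalise that depth. Its medians were 894.5 and 1002 UMIs in CD8 T E and 795 and 719 in CD8 T M. Among CD8 T E cells with no more UMIs than the median CD8 T M cell, 50.0% of 80 cells in animal 1 and 47.7% of 107 in animal 2 had a Cxcr6 count. Among CD8 T M cells with at least that many UMIs, 9.09% of 77 and 19.8% of 81 did.

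The T and NK states also differed in other receptors and effector genes. CD8 T E had more Ifng (2.85 ± 0.27), Nkg7 (1.84 ± 0.18), Ccl4 (2.68 ± 0.28), Havcr2 (2.11 ± 0.22) and Tox (2.24 ± 0.26) than the other states, and less Sell (-2.50 ± 0.18), Cxcr4 (-1.95 ± 0.20) and Ccr2 (-1.85 ± 0.21). Of 3978 genes tested, 107 were higher and 78 lower. NK cells had 197 higher and 143 lower genes. Gzma (6.17 ± 0.24), Xcl1 (3.11 ± 0.18), Gzmb (2.06 ± 0.21) and the signalling adaptors Tyrobp (3.81 ± 0.21) and Fcer1g (2.96 ± 0.20) were among the higher genes, as was Il2rb, the receptor chain shared by IL-2 and IL-15 (2455 against 1386, 0.86 ± 0.18). Cd6 (-2.35 ± 0.24) and Bcl11b (-2.05 ± 0.18), both T cell genes, were lower. Of the 18 cytotoxic effectors tested, 10 were higher, 2 lower and 6 did not pass in NK cells (12 and 2 adjusted over the list alone), and in CD8 T E 8 were higher, 2 lower and 8 did not pass (9 and 3 adjusted over the list alone).

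CD4 T R/H had 227 higher and 121 lower genes. The costimulatory receptors Tnfrsf4 (4.08 ± 0.20), Tnfrsf18 (2.21 ± 0.27), Icos (2.94 ± 0.22) and Tnfrsf9 (2.19 ± 0.23) were higher, together with the inhibitory receptor Ctla4 (3.41 ± 0.23), the IL-2 receptor alpha chain Il2ra (698 against 30.6, 3.14 ± 0.29), the transcription factor Maf (2.97 ± 0.26) and the cytokine gene Il10 (106 against 1.18, 1.58 ± 0.21). The common gamma chain list also holds signalling genes and receptors of other cytokines, such as Il18rap. Of its 14 tested genes, 4 were higher (Il7r, Il2ra, Il21r and Jak3), 1 was lower (Il18rap) and 9 did not pass (9 and 3 adjusted over the list alone). CD8 T M had 30 higher and 60 lower genes. This balance turned with a pseudocount of 200 (215 higher and 188 lower) and not with levels per 1000 cells (34 and 102) or with no block (9 and 21). The naive and memory genes Tcf7 (1.45 ± 0.21) and Ccr7 (1.05 ± 0.20) were higher, as were the T cell receptor gamma constant genes Trgc2 (1.74 ± 0.23), Trgc4 (1.65 ± 0.31) and Trgc1 (1.56 ± 0.22). Trgc1 and Trgc2 are near-identical copies that counting may split. Gzmb (-2.89 ± 0.22), Tnfrsf9 (-2.25 ± 0.21) and Icos (-1.76 ± 0.20) were lower. A count of Cd8a or Cd8b1 was present in 26.1% and 25.5% of CD8 T M cells of animals 1 and 2, against 84.6% and 87.8% of CD8 T E cells. A gamma delta T cell marker was present in 17.0% and 19.3% of CD8 T M cells and in 0% and 0.248% of CD8 T E cells. The marker list names gamma constant genes Tcrg-C1 and Tcrg-C2, where the annotated genes are named Trgc1 and Trgc2. Cells with only these genes were thus missed, so the gamma delta shares may be too low. These shares were not thinned, and the median corrected totals were those given for Cxcr6.

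The direct comparison of CD8 T E with CD8 T M asked whether Cxcr6 goes with the effector state. Cxcr6 was 1183 ± 203 in CD8 T E and 218 ± 122 in CD8 T M, a log2 fold change of 2.26 ± 0.27 (SE, n = 2 animals, adjusted p = 0.00178, limma with Benjamini-Hochberg adjustment), higher in both animals. Among the genes higher with it, Gzmb was 2181 ± 183 against 341 ± 118 (2.54 ± 0.26), Nkg7 2562 ± 352 against 753 ± 175 (1.71 ± 0.22) and Havcr2, which encodes the inhibitory receptor TIM-3, 338 ± 66.5 against 33.6 ± 18.0 (2.21 ± 0.28). Tcf7, a transcription factor of stem-like and naive T cells, was lower (14.96 ± 5.60 against 301 ± 52.0, -2.43 ± 0.25), as was Sell, the lymph node homing receptor L-selectin (-2.31 ± 0.22). Of 3978 genes tested, 88 were higher and 37 lower. Scaled per 1000 cells in place of per 1e+06 counts, 171 were higher and 35 lower, and with a pseudocount of 200, 146 were higher and 104 lower.

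Taken by gene group, 10 of 13 inhibitory receptor and exhaustion genes were higher, 0 lower and 3 did not pass (11 higher adjusted over the list alone), with Tox (1.73 ± 0.33) and Nr4a2 (1.50 ± 0.22) as the most abundant. Of 18 cytotoxic effectors 7 were higher, 0 lower and 11 did not pass (12 higher adjusted over the list alone). All 5 chemokines tested passed: Ccl4 (3.87 ± 0.35), Ccl5 (1.82 ± 0.28) and Ccl3 were higher, and Xcl1 (-1.26 ± 0.22) and Cxcl10 (-1.98 ± 0.32) lower (3 and 2 adjusted over the list alone). Of 11 chemokine and related migration receptors Cxcr6 and Cx3cr1 (1.46 ± 0.30) were higher, and Cxcr4 (-2.10 ± 0.25), Gpr183 (-1.26 ± 0.25) and Ccr7 (-1.27 ± 0.24) lower, and 6 did not pass (4 and 4 adjusted over the list alone). Among 16 stem, memory and naive T cell genes 7 were lower, 8 did not pass and 1, the costimulatory receptor Cd28 (1.12 ± 0.23), was higher (2 higher and 12 lower adjusted over the list alone). The anti-apoptotic genes Bcl2a1b (1.35 ± 0.23) and Bcl2a1d (1.22 ± 0.22) were among 4 of 14 apoptosis and survival genes that were higher, and 10 did not pass (4 higher and 1 lower adjusted over the list alone). Bcl2a1 genes are near-identical copies, so counts may be split between them.

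The remaining groups were counted in the same way. Of 15 IL-2 and IL-15 target genes Cdk6 (1.35 ± 0.28) and Prdm1 (1.27 ± 0.25) were higher, Ccnd2 was lower (-0.93 ± 0.21) and 12 did not pass (2 and 3 adjusted over the list alone). Of 14 tested genes of the common gamma chain list Il7r was lower (-1.21 ± 0.25) and 13 did not pass (1 and 1 adjusted over the list alone). Csf1 was higher (1.09 ± 0.23) among 4 cytokines that act on T cells, and 3 did not pass (1 higher adjusted over the list alone). The adhesion genes Sell and Cd69 (-1.20 ± 0.27) were lower and 16 of 18 did not pass (2 higher and 3 lower adjusted over the list alone). Of 13 dissociation and stress genes Fos (-1.31 ± 0.22) and Zfp36 (-1.39 ± 0.28) were lower and 11 did not pass (0 and 2 adjusted over the list alone). Of 5 tested genes of the costimulatory and coinhibitory ligand list only Havcr2 passed (2 higher adjusted over the list alone), a receptor gene also counted among the inhibitory receptors. None of 13 glycolysis genes passed in limma over all genes, where 7 were higher adjusted over the list alone, and the same held for 4 IL-15 trans-presentation genes (1 higher adjusted over the list alone), 17 MHC class I genes (1 higher adjusted over the list alone), 5 MHC class II genes, 26 interferon-stimulated genes and 9 proliferation genes (each 0 adjusted over the list alone). Outside the lists the largest changes were higher Gm36723 (1.74 ± 0.22), Oxsr1 (1.67 ± 0.24), Plek (1.62 ± 0.26), Twsg1 (1.62 ± 0.29) and Icos (1.60 ± 0.24), and lower Emb (-1.99 ± 0.22), Trgc4 (-1.72 ± 0.36), Treml2 (-1.72 ± 0.22), Slfn5 (-1.49 ± 0.24) and Hs3st3b1 (-1.49 ± 0.29). Gpd2 stood at 169 ± 41.3 in CD8 T E and 0 in CD8 T M, and Nsg2 at 0 in CD8 T E and 112 ± 0.947 in CD8 T M, where no count allows up to 20.9 in CD8 T M and 16.5 in CD8 T E (animal 1).

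The Cxcr6 difference missed the threshold with no filter on low genes (adjusted p = 0.11) and with a pseudocount of 10 (adjusted p = 0.102, both from limma with Benjamini-Hochberg adjustment, 1.17e-07 to 0.11 over its alternatives), at log2 fold changes of 2.26 and 2.47. With labels set anew from neighbouring cells without the list genes, Cxcr6 among them, it fell to 1.48 ± 0.23 and still passed. Cxcr6 in CD8 T M against the other T and NK states rose from 0.10 to 0.82 without passing. With CD8 T M limited to cells with Cd8a or Cd8b1 and no gamma delta marker (Trgc1 and Trgc2 not counted), Cxcr6 differed by 2.28 ± 0.38 and 11 genes passed in all. Most calls of this comparison were thus lost with the 40 CD8 T M cells kept in each animal. The counts by gene group therefore describe the whole CD8 T M state and not its CD8 cells alone.

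**Figure D2:**
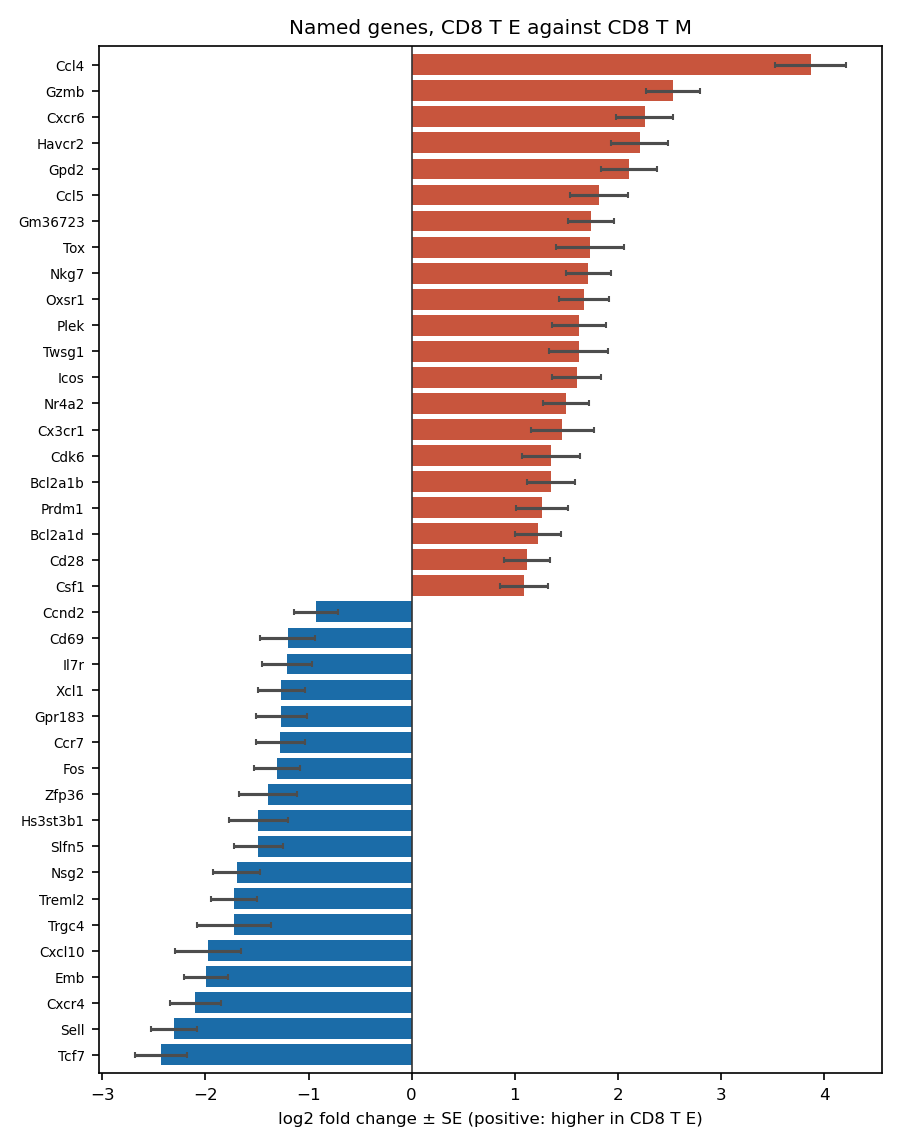
Log2 fold changes of the 39 named genes past the threshold in CD8 T E against CD8 T M (horizontal axis, positive values higher in CD8 T E), with SE from limma over 2 animals as whiskers. Of these, 21 genes were higher, up to 3.87 for Ccl4, and 18 were lower, down to -2.43 for Tcf7.

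Among the conventional dendritic cells, the question was which state carries Cxcl16, Il15 and Il15ra. Cxcl16 (ENSMUSG00000018920, GRCm38 chromosome 11, 70453983 to 70459984, minus strand) was 943 ± 240 in DC3, 396 ± 13.3 in cDC2 and 168 ± 89.8 in cDC1. Against the mean of the other 2 states, cDC1 had less Cxcl16 (-1.60 ± 0.34, adjusted p = 0.0238, limma with Benjamini-Hochberg adjustment), and the value for cDC2 was -0.11 ± 0.34 and did not pass. Of 3835 genes tested, 31 were higher and 61 lower in cDC1, and 63 higher and 26 lower in cDC2. These calls depended on the processing. In limma 0 genes passed in cDC1 and 0 in cDC2 with no filter on low genes (1418 and 1132 at an unadjusted p under 0.05), with a pseudocount of 10 (644 and 569) and with at least 30 cells per sum, where DC3 drops out (386 each). Equal weights left 10 and 4. Cxcl16 in cDC1 lost its call under each of these 4 settings, at log2 fold changes of -1.60 with no filter, -1.80 with a pseudocount of 10, -0.99 with at least 30 cells and -1.66 with equal weights. It also lost its call with pDC included (-0.35), with adjusted p-values of 0.000537 to 0.636 over its alternatives in limma. In cDC1 there were 96 higher and 96 lower genes with sums per library, 144 and 151 with all populations in the fit, and 24 and 16 with pDC included, where the balance turned. cDC1 had more Xcr1, the receptor of Xcl1 (1.79 ± 0.35), Itgae (1.80 ± 0.34) and Cd24a (2.02 ± 0.35), and less of the coinhibitory ligand Cd274 (-1.77 ± 0.33). cDC2 had more Cxcl10 (2.41 ± 0.37), Ccl4 (1.85 ± 0.35) and the antigen loading gene H2-DMb1 (1.69 ± 0.35).

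DC3 set against cDC1 and cDC2 together asked whether Cxcl16 and the genes of Il15 presentation go with the Ccr7-positive state. Cxcl16 was 943 ± 240 in DC3 and 282 ± 51.5 in the mean of cDC1 and cDC2, a log2 fold change of 1.71 ± 0.44 (SE, n = 2 animals, adjusted p = 0.0274, limma with Benjamini-Hochberg adjustment), and it was higher in both animals. Il15ra was 163 ± 48.7 against 19.9 ± 0.175 (1.69 ± 0.43, adjusted p = 0.0234 in the same limma fit with Benjamini-Hochberg adjustment), and lost its call with no filter on low genes and with a pseudocount of 10. Il15ra rested on few cells: a count was found in 2 of 14 and 6 of 40 DC3 cells of animals 1 and 2 (14.3%, exact Clopper-Pearson 95% interval 1.78 to 42.8, and 15%, 5.71 to 29.8). In cDC1 it was 2.53% (0.308 to 8.85) and 2.11% (0.256 to 7.40), and in cDC2 1.54% (0.0389 to 8.28) and 2.42% (0.502 to 6.91). Thinned to 500 corrected counts, the Il15ra shares were 0% (0 to 23.2) and 7.5% (1.57 to 20.4) in DC3, 1.27% (0.0320 to 6.85) and 2.11% (0.256 to 7.40) in cDC1, and 0% (0 to 5.52) and 1.61% (0.196 to 5.70) in cDC2. The intervals overlapped in each animal. Overlap is not a test and none was run on these shares, so whether the Il15ra shares differ stays open. Il15 itself was not testable, at 0 and 98.9 in DC3 of animals 1 and 2. Ccr7, which guides dendritic cells to lymphatics, was 4120 ± 816 against 37.6 ± 5.94 (5.62 ± 0.44), and the actin bundling gene Fscn1 3129 ± 2147 against 11.7 ± 11.7 (5.91 ± 0.48). Of 3835 genes 154 were higher and 175 lower. That balance changed with the processing. With a pseudocount of 10 there were 48 higher and 172 lower genes, 143 of them shared with the calls at 50. A pseudocount of 200 gave 154 and 109, and sums per library gave 155 and 381.

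A level of 0 in DC3 has a detection limit: no count allows a level of up to 193 per 1e+06 in animal 1 and 74.2 in animal 2 (3 counts of the total, counting error only). By gene group, Ccl22 (4.39 ± 0.55), Ccl5 (3.62 ± 0.54) and Cxcl16 were higher among 10 chemokines, Ccl6 passed as lower (0 in both animals of DC3 against 92.6 ± 64.6) and 6 did not pass (4 and 3 adjusted over the list alone). Of 9 chemokine receptors Ccr7 was higher, and Ccr1 and Xcr1, both at 0 in DC3 against 135 ± 55.7 and 122 ± 68.9, passed as lower (1 and 2 adjusted over the list alone). In animal 1 the cDC1 and cDC2 means of Ccl6, Ccr1 and Xcr1 (46.9, 95.5 and 73.1) lay under the limit, so a lower level in DC3 was not detectable there. Of 13 costimulatory and coinhibitory ligands Cd80 (2.32 ± 0.47), Cd274 (1.79 ± 0.42) and Cd200 were higher, Cd48 was lower (0 against 217 ± 21.4) and 9 did not pass (6 and 3 adjusted over the list alone). Il2ra (2.48 ± 0.45) and Il15ra were higher among 9 tested genes of the common gamma chain list and 7 did not pass (4 higher adjusted over the list alone), and Il15ra was the only passing gene of 3 tested for IL-15 trans-presentation (1 adjusted over the list alone). Of 11 IL-2 and IL-15 target genes Socs2 (4.11 ± 0.47), Il2ra and Tnfrsf4 were higher and 8 did not pass (4 higher adjusted over the list alone). Among 15 apoptosis and survival genes 4 were higher and 11 did not pass (4 higher adjusted over the list alone), with Bcl2a1b at 3371 ± 607 against 726 ± 33.6 (2.09 ± 0.43) and Bcl2a1d at 2.04 ± 0.44. Of 14 MHC class II presentation genes 4 were lower, including the class II transactivator Ciita (-1.76 ± 0.44) and H2-DMa (-1.72 ± 0.43), and 10 did not pass (2 higher and 7 lower adjusted over the list alone).

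Further groups were counted in the same way. Of 13 adhesion genes Fscn1 and Itga4 (1.49 ± 0.43) were higher, 3 were lower, with Itgb2 (-2.71 ± 0.44) and Itgax (-1.91 ± 0.46) the most abundant, and 8 did not pass (3 and 4 adjusted over the list alone). The granzyme inhibitors Serpinb6b (3.43 ± 0.45) and Serpinb9 (3.05 ± 0.44) were higher among 7 members of the cytotoxic list (3 higher adjusted over the list alone). Nr4a3 (2.17 ± 0.48) and Tnfrsf9 (2.01 ± 0.44) were higher among 7 exhaustion list genes (2 higher and 2 lower adjusted over the list alone), and Ccr7 and Tcf7 (2 and 3 counts in DC3 against 0) among 6 stem and naive list genes (3 higher adjusted over the list alone). Fos (-1.97 ± 0.43), Atf3 (0 against 178 ± 75.4) and Ier3 (0 against 107 in cDC1 and 90.2 in cDC2, under the limit of animal 1) passed as lower among 15 dissociation and stress genes (3 lower adjusted over the list alone), Ifitm3 (-1.68 ± 0.42) and Isg20 (-2.17 ± 0.42) among 33 interferon-stimulated genes (2 lower), Calr (-1.69 ± 0.43) among 17 MHC class I genes (1 lower), Ldha (-1.69 ± 0.47) among 15 glycolysis genes (1 lower) and Pcna (-1.83 ± 0.45) among 6 proliferation genes (1 lower), all counted again when adjusted over the list alone. None of 2 cytokines that act on T cells passed in limma (0 adjusted over the list alone). Outside the lists, Tbc1d4 (3.93 ± 0.43), Samsn1 (3.62 ± 0.42), Fabp5 (3.20 ± 0.50), Rgs1 (3.17 ± 0.43), Flrt3 (3.03 ± 0.43) and Ramp3 (3.02 ± 0.44) were higher, and Plbd1 (-3.23 ± 0.44), Olfm1 (-3.21 ± 0.54), Ms4a6b (-3.01 ± 0.42), Gsn (-2.97 ± 0.52), Gm2a (-2.82 ± 0.43) and Ppt1 (0 against 407 ± 16.9) lower.

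The Cxcl16 difference missed the threshold with no filter on low genes (adjusted p = 0.13) and with a pseudocount of 10 (adjusted p = 0.131, both from limma with Benjamini-Hochberg adjustment, 0.00262 to 0.131 over its alternatives), and DC3 of animal 1 held only 14 cells. A Cxcl16 count was found in 42.9% and 47.5% of DC3 cells of animals 1 and 2 (medians 1195.5 and 891.5 corrected counts), in 27.7% and 33.1% of cDC2 cells (1125 and 1207), in 6.33% and 17.9% of cDC1 cells (868 and 1173) and in 0.549% and 0.993% of CD8 T E cells as background (922 and 980). Thinned to 500 corrected counts with 0 cells left out, the shares were 14.3% (exact Clopper-Pearson 95% interval 1.78 to 42.8) and 22.5% (10.8 to 38.5) in DC3, 15.4% (7.63 to 26.5) and 20.97% (14.2 to 29.2) in cDC2, 3.80% (0.790 to 10.7) and 9.47% (4.42 to 17.2) in cDC1, and 0.549% and 0.993% in CD8 T E. The intervals of DC3 and cDC2 overlapped in each animal, and no test was run on these shares, so whether they differ stays open.

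**Figure D3:**
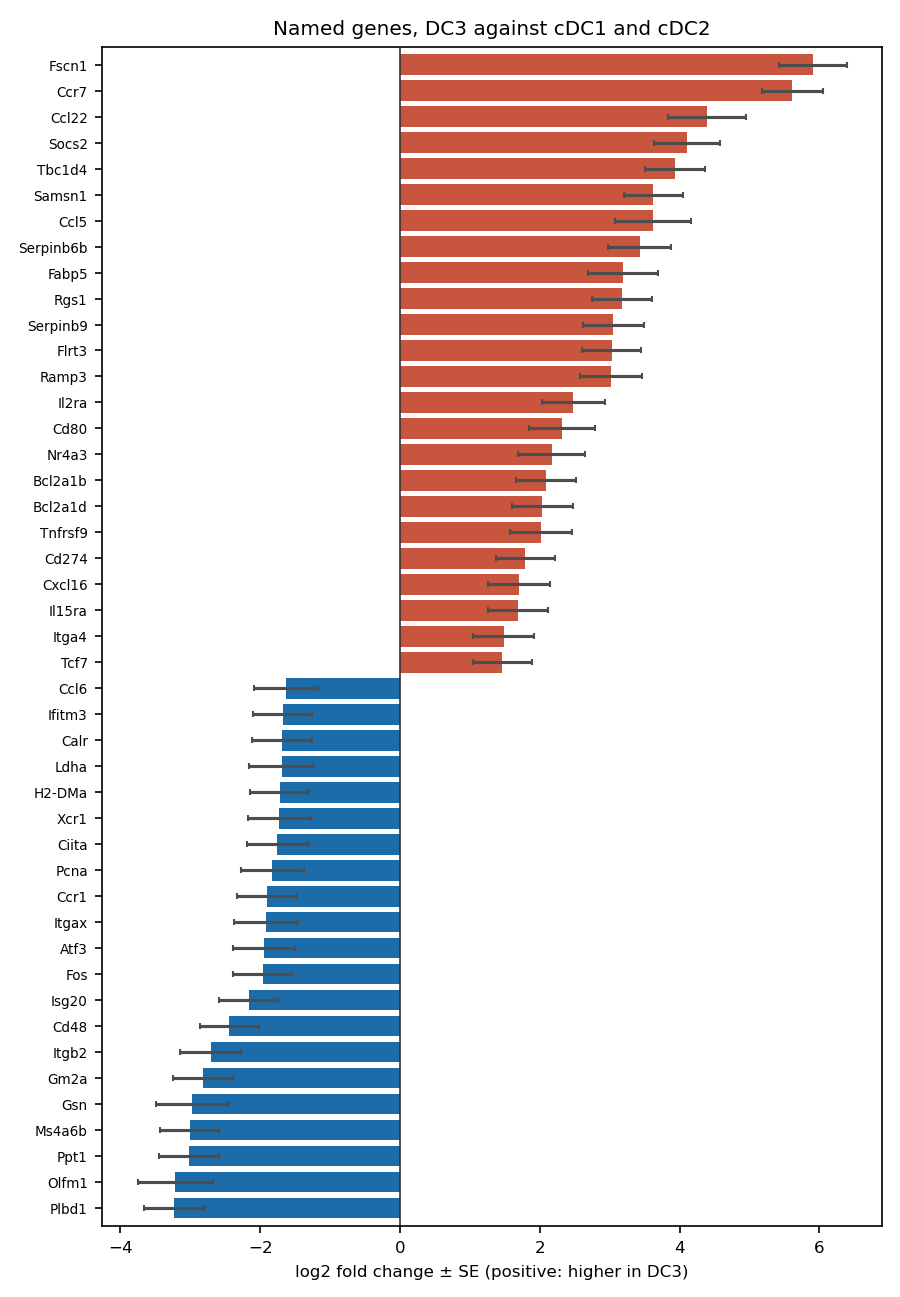
Log2 fold changes of the 45 named genes past the threshold in DC3 against cDC1 and cDC2 (horizontal axis, positive values higher in DC3), with SE from limma over 2 animals as whiskers. Of these, 24 genes were higher, up to 5.91 for Fscn1, and 21 were lower, down to -3.23 for Plbd1.

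The same questions were asked of the 10435 barcodes of the UMI matrices that passed filters, which by barcode and expression could not be matched to the annotated cells. In clusters rebuilt from these counts, Cxcr6 was 922 and 598 UMIs per 1e+06 in effector or exhausted CD8 T-like cells of animals 1 and 2 and 188 and 126 in stem or naive T-like cells, a log2 fold change of 2.19 ± 0.31 (SE, n = 2 animals, adjusted p = 1.29e-08, edgeR with Benjamini-Hochberg adjustment). The stem or naive T-like cluster was led by Tcf7 and Lef1 and also by the gamma delta genes Trdc, Tcrg-C1, Tcrg-C2 and Tcrg-C4, and Cxcr6 was among the leading genes of the effector cluster. Of 3161 genes 123 were higher and 139 lower. Of the 101 genes past the threshold in annotated CD8 cells that were tested here, 94 had the same direction, 65 also passed in that direction (4.47 expected for independent lists) and 1 passed in the opposite direction. That gene was Ccr7. It stood at 357 and 266 UMIs per 1e+06 in the effector cluster against 127 and 135 (1.19 ± 0.41, adjusted p = 0.0494, edgeR with Benjamini-Hochberg adjustment, 0.0471 to 0.304 over its alternatives), where the annotated cells gave -1.27. A minority of cells carried these Ccr7 values. In the effector cluster 60 and 32 UMIs lay in 11.5% of 157 and 10.5% of 114 cells. In the stem or naive T-like cluster 21 and 15 UMIs lay in 7.55% of 212 and 6.37% of 157 cells. In DC3-like cells, Cxcl16 was 1022 and 610 per 1e+06 against 610 and 600 in the mean of the other 6 clusters of the dendritic group, pDC-like cells left out (log2 fold change 0.70 ± 0.24, adjusted p = 0.0201, edgeR with Benjamini-Hochberg adjustment, 0.00462 to 0.264 over its alternatives). The levels were nearly equal in animal 2 (610 against 600), so this difference came mainly from animal 1. Among the other clusters was an unnamed cluster led by the macrophage markers C1qa, C1qb and Apoe, with 927 and 981 Cxcl16 UMIs per 1e+06. It had no dendritic marker raised, but neither had some other unnamed clusters that were kept. A kept cluster of this kind stood at 582 and 988, above DC3-like cells in animal 2. Without the cluster led by macrophage markers the mean was 547 and 524, and Cxcl16 differed by 0.86 ± 0.25. Whether the difference is smaller than in the annotated cells was not tested. The call was lost with no filter (0.58) and in the DESeq2 test (0.74). Ccr7 was 5019 and 4533 against 36.0 and 38.6 (7.67 ± 0.23). Against DC1-like cells alone Cxcl16 differed by 0.92 ± 0.33 (adjusted p = 0.0375, edgeR with Benjamini-Hochberg adjustment, 0.0116 to 0.359 over its alternatives). That call was lost with no filter (0.84), with no block (0.92) and in the DESeq2 test (1.03). Of 2009 genes 324 were higher and 280 lower in DC3-like cells, and of 238 genes past the threshold in annotated DC3 that were tested here, 185 passed in the same direction (35.4 expected for independent lists) and 0 in the opposite direction in edgeR. Both sets come from the same 2 animals, and the clusters were named from markers of the same cell types. Overlaps above those of independent lists were thus bound to arise, for CD8 cells and for DC3, and are no separate support.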

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

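The depth tests were chosen after the shares of all cells with a count had been seen. Labels set anew were an alternative fixed before the data were examined, and their use here as a test was chosen after its value was seen. The limit of CD8 T M to CD8 cells was chosen after the data, but not its result, had been seen. A library was picked out when its distance from the next was large against the range of all 8 libraries. Chance picks out about 1 in 20 groups of libraries. The percent of cells in Neu was 0.614 in library 2 of animal 2 and 0 to 0.214 in the other 7 libraries. The Cxcl16 level in DC3 was 4269 per 1e+06 in library 3 of animal 1 and 0 to 1318 in the other 7. DC3 made up 0.123% of the 815 annotated cells of library 3 of animal 1, its lowest share over the 8 libraries. That share is 1 cell, so the level of 4269 is that of 1 of the 14 DC3 cells of animal 1. In DC3 of animal 1 as a whole, 1 count equals 64.4 per 1e+06. The Cxcl16 difference without that library was not computed.

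Cxcr6 was higher in CD8 T E than in CD8 T M. Cells other than CD8 T cells in CD8 T M might lower its Cxcr6 level there. With CD8 T M limited to cells with Cd8a or Cd8b1 and no gamma delta marker the log2 fold change was 2.28 ± 0.38 (adjusted p = 0.0398, limma with Benjamini-Hochberg adjustment, 1.17e-07 to 0.11 over its alternatives). This argues against cells without a Cd8a or Cd8b1 count as the whole cause. The marker rule kept 40 of the 40 CD8 T M cells with Cd8a or Cd8b1 in animal 1 and 40 of 41 in animal 2. It did not count Trgc1 and Trgc2, so gamma delta T cells with a Cd8a or Cd8b1 count stay open. A difference in depth was tested with cells chosen by UMI total. CD8 T E cells with no more UMIs than the median CD8 T M cell were set against CD8 T M cells with at least that many. The share with a Cxcr6 count was higher in the CD8 T E cells, and the smaller gap between the exact intervals was 7.83 percentage points. These were corrected counts, which follow depth only in part, so depth need not favour CD8 T M and the test does not decide. In the UMI set, cells of 500 or more UMIs were thinned to 500 UMIs. A Cxcr6 UMI then remained in 32.4% and 28.7% of effector or exhausted CD8 T-like cells of animals 1 and 2. In stem or naive T-like cells it was 7.01% and 3.54%, which argues against depth as the whole cause in that set. Cxcr6 itself may have helped to define the states. With labels set anew from neighbouring cells, found without the list genes and so without Cxcr6, the log2 fold change was 1.48 ± 0.23 (adjusted p = 0.00793 in limma with Benjamini-Hochberg adjustment, same range), which argues against the list genes in the labels as the whole cause. A part stays open, since the fold was smaller than the reported 2.26 and the new labels were still taken from the authors' labels of the neighbours. No biological explanation was tested.

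Cxcl16 was higher in DC3 than in the mean of cDC1 and cDC2. Macrophages are the main carriers of Cxcl16, so macrophage RNA or macrophages among the DC3 cells could raise it. The median of 8 macrophage markers in DC3 was 0% of the Mac1 level in animal 1 and 6.58% in animal 2, where 78.2% and 104% would be needed, which argues against this. A difference in depth stays open. The median DC3 cell had 1261.5 UMIs in animal 1, more than the 976 of cDC1 and cDC2 together. In animal 2 it had 784, fewer than 1315, so that higher Cxcl16 in DC3 (1112 against 318 per 1e+06) went with less depth there. Depth alone would thus have to act in opposite directions in the 2 animals, but animal 1 had only 14 DC3 cells, and 1 animal excludes nothing. A Cxcl16 count was found in 20% of 5 and 40.6% of 32 DC3 cells with no more UMIs than the median cell of cDC1 and cDC2. It was found in 22.2% and 30.9% of the cDC1 and cDC2 cells with at least that many UMIs. The exact intervals overlapped in both animals, with a lowest gap of -33.1 percentage points. After thinning to 500 corrected counts, the shares in DC3 (14.3% and 22.5%) also overlapped with those in cDC2 (15.4% and 20.97%). The cells are too few to decide, and no biological explanation was tested.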

How the results depend on the processing

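The limma settings (pseudocounts, weights, scale, only the CD8 states, CD8 T M limited to CD8 cells) and the tests on the UMI set were chosen after the data had been seen, the other alternatives before. Of 8271 tested comparisons of a named gene's value with its reported one, 7130 kept direction and side of the threshold, 1110 lost the call, 11 gained it and 20 reversed. Of 1640 values with an animal left out, which have no test, 9 reversed. Cxcr6 kept its direction in CD8 T E against CD8 T M under every alternative run, as did Cxcl16 in DC3. Cell numbers limit DC3, with 14 cells in animal 1. The cause of the changes that follow was not tested. DESeq2 was not run on annotated cells because their values are not counts. Contrasts with DC3 have no value at 30 cells or more, and no test can be made without an animal.

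With no filter, Cxcr6 in CD8 T E against CD8 T M had a log2 fold change of 2.26 and lost its call (adjusted p = 0.11, limma with Benjamini-Hochberg adjustment, 1.17e-07 to 0.11 over its alternatives), as did Cxcl16 in DC3 at 1.71 (0.13, 0.00262 to 0.131). The UMI set gave 0.84 for Cxcl16 in DC3-like against DC1-like cells and 0.58 against the other dendritic clusters, also without a call. Genes past the threshold numbered 11 for CD8 T E against CD8 T M, 43 for DC3, 98 for CD4 T R/H, 23 for CD8 T E, 3 for CD8 T M, 137 for NK, and in the UMI set 255 for DC3-like against DC1-like and 155 for CD8. limma gave 0 for cDC1 and 0 for cDC2, with 1418 and 1132 at an unadjusted p under 0.05. With a pseudocount of 10, Cxcr6 was 2.47 and Cxcl16 1.86 without a call, and the counts were 21, 220 for DC3 (48 higher and 172 lower), 203 for CD4 T R/H, 76 for CD8 T E, 28 for CD8 T M, 221 for NK, and in limma 0 for cDC1 and 0 for cDC2 (644 and 569 at an unadjusted p under 0.05). Reversed were Cxcr6 (0.13) and Il15ra (-0.13) in B cells, Cxcr6 in NK cells (0.22) and Ccr7 in T cells (0.53). With 200 the counts were 250 for CD8 T E against CD8 T M, 531 for CD4 T R/H and 403 for CD8 T M (215 higher and 188 lower), and Cxcr6 in CD8 T M reversed to -0.14.

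With all populations in the fit, which also gave more false calls in simulated data, the counts were 392 for CD8 T E against CD8 T M, 577 for DC3, 724 for CD4 T R/H, 380 for CD8 T E, 551 for CD8 T M, 558 for NK, 295 for cDC1 and 302 for cDC2. Without the animal as a replicate block they were 82 for CD8 T E against CD8 T M, 216 for CD4 T R/H, 30 for CD8 T M and 163 for CD8 in the UMI set, where Cxcl16 against DC1-like cells (0.92) lost its call, and without the block no other count moved by over 1.5 times and no other Cxcr6 or Cxcl16 call of the main comparisons changed. Sums per library gave 341 for CD8 T E against CD8 T M, 536 for DC3, 305 for CD8 T E, 405 for CD8 T M, 192 for cDC1, 244 for cDC2, and in the UMI set 154, 202 and 138 for DC3-like against DC1-like, against the others and CD8. Cxcl16 in cDC2 (0.10) and Il15ra in B cells (-0.15) reversed.

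With at least 30 cells limma gave 0 for cDC1 and 0 for cDC2 (386 each at an unadjusted p under 0.05), and reversed Cxcl16 in cDC2 (0.99), Cxcl10 in dendritic cells (-0.0281), Dusp1 in NK cells (-0.006), T cells (-0.0126) and macrophages (-0.0755), Gbp7 in NK cells (-0.0877), and Ccr7 (0.0419) and Sell (0.20) in T cells. Levels per 1000 cells gave 206 for CD8 T E against CD8 T M, 136 for CD8 T M and 134 for cDC2, and Il15ra in B cells at -0.0079. Equal weights gave 737 for DC3, 10 for cDC1 and 4 for cDC2, and Il15ra in B cells at -0.002. Labels set anew lowered Cxcr6 in CD8 T E against CD8 T M from 2.26 to 1.48, still called, and gave Cxcr6 in CD8 T M at 0.82, 53 genes for CD8 T M and 52 for cDC2, Cxcr6 in B cells at 0.57 and Ccr7 in T cells at 0.0049. Only the 2 CD8 states gave 340, and CD8 T M limited to CD8 cells 11. With pDC included, cDC1 had 40 and Cxcl16 in cDC2 was 0.99.

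The DESeq2 test gave 230 for DC3-like against DC1-like, 364 against the others and 134 for CD8, and Cxcl16 at 1.03 and 0.74 without a call. The mean over 8 libraries put non-immune cells at 17.1%. The thinned share gave a log2 ratio of 0.57 for Cxcl16 in DC3 to cDC1 and cDC2, where levels gave 1.73. With an animal left out, the ranges were 1.96 to 2.58 for Cxcr6 in CD8 T E against CD8 T M and 1.66 to 1.70 for Cxcl16 in DC3. They crossed 0 for Cxcr6 in B cells (-0.58 to 0.28), NK cells (-0.40 to 0.0749) and CD8 T M (-0.24 to 0.41), Tcf7 in B cells (-0.65 to 0.37), Il15ra in T cells (-0.11 to 0.44) and B cells (-0.54 to 0.54), Cxcl16 in cDC2 (-0.33 to 0.29), Ccr7 in T cells (-0.37 to 0.29) and Ifi47 in pDC (-2.81 to 0.66).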

Other observations

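The genes of this part were described after their values were seen. In cDC2, 6 of 33 interferon-stimulated genes were higher than in cDC1 and DC3, 0 lower and 27 did not pass in limma with Benjamini-Hochberg adjustment (23 higher adjusted over the list alone). Ifit3 was 420 ± 50.3 against 50.3 ± 38.4 (log2 fold change 2.53 ± 0.38, SE, n = 2 animals) and Irf7 639 ± 143 against 174 ± 11.6 (1.78 ± 0.34). Cxcl10, an interferon-induced chemokine, was 842 ± 135 against 187 ± 157 (2.41 ± 0.37). The stress genes Fos and Atf3 were also higher in cDC2. All of these calls were lost with no filter, with at least 30 cells per sum and with a pseudocount of 10. Those of Ifit3, Irf7 and Cxcl10 were also lost with equal weights, and that of Irf7 with labels set anew, while these 3 genes kept their direction under every alternative run. No set test was run.

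In CD4 T R/H, the cytokine gene Ebi3 (77.6 ± 25.3 against 0.745 ± 1.05, log2 fold change 1.30 ± 0.20), the integrin gene Itgae (1.74 ± 0.26) and Klrg1 (2.33 ± 0.20) were higher than in the other T and NK states. Nkg7 (-1.95 ± 0.20) and Gzma (-2.34 ± 0.27) were lower, all by limma with 2 animals.

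Mast cells numbered 57 in animal 1 and 2 in animal 2 among the annotated cells (1.71%, exact Clopper-Pearson 95% interval 1.30 to 2.21, and 0.0369%, interval 0.00447 to 0.133). In the UMI set, a cluster of mast or basophil cells held 67 and 32 barcodes.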
